A study of Mus musculus with 9 samples.

How the data were processed

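The series measured transcripts in mouse hippocampus on 9 two-colour oligonucleotide arrays. Per the labels, RNA came from single hippocampi of 8 female mice, 2 in each of 4 groups: wild-type (WT) at 3 months, WT at 12 months, 3xTG at 3 months and 3xTG at 12 months. 3xTG is a mouse line carrying mutant human transgenes, those of APP and tau among them. RNA was linearly amplified, and the test and reference samples of each array were labelled with Cy5 or Cy3, per the labels' protocols. There were 3 comparisons with 3 arrays each. Arrays were assigned to 2 slide runs: all those of WT at 12 over 3 months to the first, and those of 3xTG over WT at either age to both. The test RNA was in Cy5 on 3 arrays and in Cy3 on 6 arrays, so each comparison held both dye orientations unequally. Arrays shared mice, and the series design text counts 6 arrays as biological and 3 as technical replicates.

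The values used are the deposited log2 ratios of 29922 probes. The scanner, background correction, filter and normalization behind them are not given in the sources used here, and scanner intensities were not used here. Each array listed between 45.7 and 54.1% of the probes, and 142 probes had a value on all 9 arrays. No listed value lay between -0.5 and 0.5, so small ratios are missing along with any spots left out for other reasons, and both look alike in the table. Array medians ran from -1.71 to 2.34. Signal over background is unknown, and the number of arrays limits the precision.

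The analysis fixed before the data were examined took the ratios to be normalized by the authors and used them without centring. The medians contradicted that. Each array was therefore centred on the median of its listed values, a setting that had been planned as an alternative. This change was made after the values had been seen and after trial fits had been run both with and without centring. Counts of probes under the fixed setting are given beside each comparison, with its medians for most lists named. Scale and direction were taken from the values and labels: the ratio was read as test over reference. Arrays of opposite dye orientation within a comparison correlated positively across probes, at 0.197 to 0.308. The reading as Cy5 over Cy3 would make this negative unless dye bias of single probes outweighed it. Under that reading such bias would make arrays of different comparisons correlate positively too. The 9 pairs of WT at 12 over 3 months with 3xTG over WT at 12 months correlated at -0.160 to -0.073. These pairs hold equal and opposite dye orientations. The overall sign rests on the labels alone.

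Probes entered if they were listed on at least 2 of the 3 arrays of each comparison, which left 3696, of which 3644 could be fitted. Ratios were fitted in limma 3.58.1 (R 4.3.3) by generalised least squares with a coefficient for each comparison and a single dye term. This left 5 residual degrees of freedom for the 142 probes listed on all arrays, and fewer for probes with missing values. The covariance between arrays was built from shared mice, with a ratio of between-mouse to between-array variance of 1.02, estimated by restricted maximum likelihood on the 142 complete probes. For gene means the ratio was 0.115 over 516 complete genes, so this ratio is itself uncertain. Moderated statistics came from eBayes, with Benjamini-Hochberg adjustment and a threshold of 0.05. Besides the 3 hybridised comparisons, 2 contrasts were derived: the genotype effect at 12 months minus that at 3 months, and 3xTG at 12 months over 3xTG at 3 months through the WT mice.

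A single gene symbol was given for 21020 probes and none for 8902. Of 16675 symbols, 13905 were current in the RefSeq table of assembly GRCm38.p6, 2728 were updated through a synonym and 42 were kept as annotated. Of 46 gene lists fixed before the data were examined, 30 had at least 5 tested genes among 3944. The planned camera test needs complete values, and no list had 5 genes among the complete probes. In its place cameraPR was run on moderated statistics of gene means, with a preset inter-gene correlation of 0.01. This choice was made after seeing the data, when trial results with and without the filter on missing values had been seen. The fry test also needs complete values and was not run. Genes named are the transgene-related genes, then in each direction the probes past the adjusted threshold with one sign on all 3 arrays. Where too few passed, places were filled by the probes of smallest p that also had one sign on all 3 arrays. In lists, up to 4 genes of smallest p are named. For the derived contrasts, the probes named also needed one sign on all 3 arrays of each comparison that enters the contrast. The fixed rule left this open, and this reading was settled after the data had been seen, for 3xTG at 12 over 3 months after a looser one had been tried. No filled place passed. A gene that the rule names is not reported here.

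Alternatives covered the covariance, the dye term, the choice of arrays, centring, scaling, missing values, probe averaging, the variance prior, the sign and leaving out each array, 25 settings per probe result with the one reported. Centring on 5 lists of abundant transcripts (respiratory complex I, complexes II to V, glycolysis, cytosolic ribosomal proteins and proteasome), on the tested probes or with the empty range taken into account was added after seeing the data. The setting fixed beforehand, without centring, was run as an alternative. The fit was tested on simulated data with the real missing values, 10 simulations with 200 changed probes in each comparison. Of the 66 probes changed by a log2 of 4 in each simulation, the share called was 0.455% for WT at 12 over 3 months, 0.303% for 3xTG over WT at 3 months and 0.152% for 3xTG over WT at 12 months, from fits of 3644 probes. With values between -0.5 and 0.5 also taken out of the simulated data, which left 1673.1 probes on average, the shares among 29.8, 40.2 and 39.4 such probes on average were 0.40%, 3.20% and 2.31%. The fit therefore has little power to call single probes, although without that step fitted log2 changes averaged 3.87, 4.00 and 4.03. Unchanged probes reached an unadjusted p under 0.05 in 5.61%, 5.59% and 5.25%, and in 5.54%, 7.50% and 6.02% with that step. With 2 mice per group and shared mice between arrays, p-values measure only the spread between these mice and arrays.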

Results

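Transcript levels in hippocampus were compared between WT mice of 12 and 3 months, and between 3xTG and WT mice at each age. Each comparison rests on 3 arrays and 2 mice per group. Between 13683 and 16191 probes were listed per array. Before centring, array medians were 1.42, 2.34 and 1.96 for WT 12 over 3 months, 0.84, -0.84 and 0.97 for 3xTG over WT at 3 months, and -0.87, -0.87 and -1.71 at 12 months. The 5 lists of abundant transcripts had positive medians on all arrays, 0.56 to 1.88. Olfactory, vomeronasal and taste receptors and keratin-associated proteins, families chosen after seeing the data as unlikely to be expressed in hippocampus, had medians from -2.06 to 2.85. Log2 values below are relative to the array median. Centring on the abundant transcripts instead moved the median fitted log2 ratio of all tested probes from -0.14 to 0.40 for WT ageing, from 0.11 to -0.72 for genotype at 3 months and from 0.58 to -1.61 for genotype at 12 months.

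**Figure D1:**
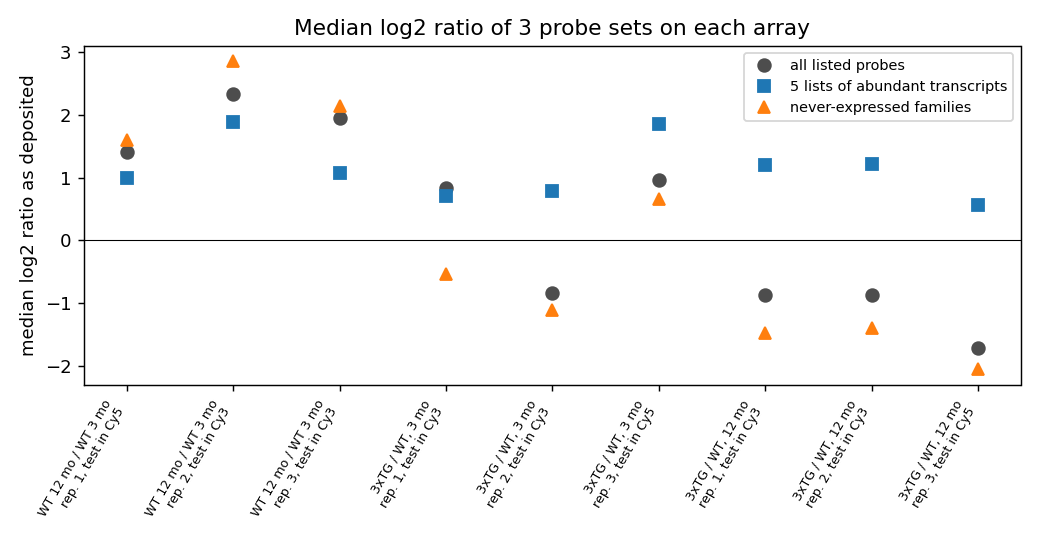
Median deposited log2 ratio (vertical axis) of all listed probes, of the 5 lists of abundant transcripts and of the never-expressed families on each of the 9 arrays (horizontal axis, with replicate and test dye). The abundant transcripts lie between 0.56 and 1.88 on every array, while the median of all listed probes runs from -1.71 to 2.34.

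The first comparison asked which transcripts differ between WT hippocampus at 12 and at 3 months. No probe passed, so the values that follow describe the probes of smallest p among those with one sign on all 3 arrays. Among them, Meg3, a maternally expressed long non-coding RNA, had a log2 ratio of -4.12 ± 0.75 (SE, n = 3 arrays, limma adjusted p = 0.276). Dlgap1, a postsynaptic scaffold protein, was at -3.97 ± 0.83 (SE). Ip6k1, an inositol hexakisphosphate kinase, was at -4.67, Eif3f, a translation initiation factor subunit, at -4.57, Vav2 at -7.78, Pa2g4 at -5.62, Rnf6 at -4.69, Mrpl12 at -3.73, Hip1r at -4.15 and Psmd3 at -4.18. On the other side, Sbf1 was at 6.16 ± 1.14 (SE), Wtap, a component of the RNA methylation complex, at 3.91, Dnajb9, a chaperone of the endoplasmic reticulum, at 2.68, and Neurod1, a neuronal transcription factor, at 2.67. Rit2 was at 2.18, Serbp1 at 3.81, Cd200 at 2.87, Rpgrip1 at 3.79, Cav2 at 2.52 and Osbpl1a at 2.45. Each of these probes had one sign on all 3 arrays and kept it without centring and with centring on the abundant transcripts. Without centring the 10 above 0 ran from 4.03 to 7.99 and the 10 below 0 from -5.94 to -1.88.

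No gene list was called in this comparison by cameraPR. Glutamate receptors and postsynaptic density had 7 of 10 genes below 0 and a median of -0.43 (cameraPR adjusted p = 0.559, and 0.845 with an estimated correlation). The median was 0.04 when arrays were centred on the abundant transcripts and 1.43 without centring. In these 3 settings the median of all genes tested was -0.15, 0.41 and 1.74, so the median of the list lay below it in each. Centring shifts all genes of an array alike, so the 3 settings are not separate support for this. Over all genes tested 0 of its genes passed, and 2 passed adjusted over the list alone; Gria1, an AMPA receptor subunit, was at -3.62 and Grin2a, an NMDA receptor subunit, at -2.97. Tau, tau kinases and microtubules had 8 of 11 genes below 0, with a median of -2.11 (adjusted p = 0.559, and 0.845 with an estimated correlation), or -0.44 without centring and -1.45 relative to the abundant transcripts, and 1 gene passing adjusted over the list alone against 0 over all genes tested. Its Map4, a microtubule-associated protein, was at -3.85, Csnk1e at -2.47, Kif5c, a kinesin heavy chain, at -2.88 and Tubb5 at -2.65. limma called 0 of 3644 probes, with 431 at an unadjusted p under 0.05 (84 above and 347 below 0) where the nominal rate gives 182.2. Unchanged simulated probes exceeded that rate, at 5.61% and 5.54%, and probes are not independent, so 182.2 is a rough guide. Without centring, as fixed before the data were examined, limma also called 0, with 710 at an unadjusted p under 0.05, 673 of them above 0. Treating arrays as independent gave 66 calls, 5 above and 61 below 0, a fit that disregards the shared mice.

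The second comparison asked which transcripts differ between 3xTG and WT hippocampus at 3 months. No probe passed. Nrn1, which encodes neuritin, a neurite outgrowth factor, had a log2 ratio of 5.0 ± 0.92 (SE, n = 3 arrays, limma adjusted p = 0.242). B2m, the light chain of MHC class I, was at 4.69 ± 0.77 (SE), and Pkia, an inhibitor of protein kinase A, at 5.31 ± 0.88 (SE). Plppr4 was at 5.15, Pdha1, a subunit of pyruvate dehydrogenase, at 5.22, Car2, a carbonic anhydrase, at 4.04, Rida at 4.61, Hnrnpa0 at 4.01, Tmem59 at 3.75 and Klhl7 at 4.51. Below 0 were Emc10 at -3.74, Csnk1g2 at -3.65, Rnf208 at -3.22, Klk10 at -4.77, Trim8 at -2.75, Scand1 at -4.60, Baiap2 at -3.81, Fam98c at -3.77, Map2k2 at -3.13 and Ubtf at -3.13. All kept their sign without centring and with centring on the abundant transcripts. WT ageing has the same WT mice of 3 months as reference. There the probes named above 0 were also above 0, from 0.53 (Pdha1) to 3.22 (Klhl7). Those named below 0 ran from -5.08 (Csnk1g2) to -2.98 (Trim8), except Klk10 at 1.10. For these probes the results are therefore not separate. A genotype effect cannot be told apart from levels particular to the shared WT mice.

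The probes of the transgene-related genes are annotated to mouse genes, and whether they detect the human transgene transcripts was not tested. One App probe had a log2 ratio of 2.65 ± 0.89 (SE, limma adjusted p = 0.26) at 3 months and 2.14 ± 0.88 (SE, limma adjusted p = 0.26) at 12 months. Without centring it was at 3.23 and 0.98, and relative to the abundant transcripts at 2.04 and 0.01. A second App probe did not enter the test; its fitted log2 ratio was 4.46 ± 1.28 (SE, 2 arrays) at 3 months and 1.92 ± 1.57 (SE, 2 arrays) at 12 months, or 4.53 and 1.95 without centring and 3.21 and 0.20 relative to the abundant transcripts. Thy1, whose regulatory sequence drives transgenes in this line, was at 0.90 ± 0.89 (SE) and 2.27 ± 0.89 (SE), or 1.47 and 1.09 without centring and 0.26 and 0.10 relative to the abundant transcripts. Mapt, the gene of tau, did not enter the test; at 12 months its 3 arrays gave 2.69 ± 0.31 (SD, n = 3), or 0.54 ± 0.40 (SD) relative to the abundant transcripts. At 3 months only 1 array listed Mapt, at -0.16, or -0.031 relative to the abundant transcripts. Without centring the fitted log2 ratio of Mapt was 0.34 at 3 months and 1.41 at 12 months.

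No list was called at 3 months by cameraPR. Pyramidal cells of CA1 to CA3 had 5 of 5 genes above 0 with a median of 1.84, or 2.25 without centring (adjusted p = 0.169), among them Nptx1, a neuronal pentraxin, at 3.65 and Crym at 1.83. Neurotrophins and plasticity had 6 of 7 genes above 0 (cameraPR adjusted p = 0.178), with Gap43, a growth cone protein, at 5.88. The median of the list was 0.60, or 1.04 without centring and -0.24 relative to the abundant transcripts. That of all genes tested was 0.12, 0.39 and -0.71 in these 3 settings, so the median of the list lay above it in each, which centring hardly affects. In these 2 lists, 1 and 2 genes passed adjusted over the list alone, and 0 over all genes tested. Collagens had 10 of 12 genes below 0 with a median of -1.47, or -1.12 without centring (adjusted p = 0.189), Col9a1 being at -2.74. limma called 0 of 3644 probes, with 492 at an unadjusted p under 0.05 (334 above and 158 below 0). Without centring it called 0, with 469 above and 82 below 0 at an unadjusted p under 0.05. Centred on the abundant transcripts it called 0, with 225 above and 452 below 0, so the overall direction turned here too. Treating arrays as independent gave 56 calls, 52 of them above 0.

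The third comparison asked the same of genotype at 12 months. Of the lists tested by cameraPR, 1 was called: complex I of the respiratory chain rose against the other genes, with 11 of 12 genes above 0 and a median of 2.18 (adjusted p = 0.0319, and 0.0337 with an estimated correlation). Ndufs4 was at 3.45 ± 0.78 (SE), Ndufc2 at 3.42 ± 0.84 (SE), Ndufa4 at 3.19 ± 0.80 (SE) and Ndufa9 at 2.39 ± 0.81 (SE). Adjusted over the list alone 5 genes passed, and 0 over all genes tested. Without centring, the setting fixed before the data were examined, the adjusted p was 0.0522 and no list was called, and centred on the abundant transcripts, which include these genes, it was 0.119. The median of the list lay 1.71 above that of all genes tested, 1.87 above it without centring and 1.85 above it with centring on the abundant transcripts, while the median itself was 1.18 and 0.14 in these 2 settings. Centring shifts all genes of an array alike, so these 3 distances are not separate support. The call also ended without each of 5 of the 9 arrays, with cameraPR adjusted p up to 0.183.

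The other lists of abundant transcripts lay above the array median too: glycolysis at 1.85 (adjusted p = 0.102), cytosolic ribosomal proteins at 2.19 (adjusted p = 0.227), complexes II to V at 1.30 (adjusted p = 0.262) and proteasome at 1.15 (adjusted p = 0.742). Without centring their medians were 0.88, 1.04, 0.07 and 0.01, against -0.69 for all genes tested. Centring on the 5 lists sets their pooled median near 0, so the signs of these lists under it carry no information. Without the filter on missing values, a setting chosen after seeing the data, cameraPR called proteasome (18 genes, median 2.55, adjusted p = 0.00014) and complexes II to V (19 genes, median 2.15, adjusted p = 0.0199). In that setting no cell type list was called. Markers of pyramidal cells of CA1 to CA3 had a median of 1.89 (12 genes, cameraPR adjusted p = 0.210). Those of granule cells of the dentate gyrus were at -0.27 (11 genes, cameraPR adjusted p = 0.465). Amyloid precursor processing and clearance had 12 of 12 genes above 0 and a median of 1.95 (cameraPR adjusted p = 0.0624). The median was 0.74 without centring and -0.21 relative to the abundant transcripts. In these 3 settings the median of all genes tested was 0.48, -0.69 and -1.71, so the median of the list lay above it in each, which centring hardly affects. Its Apoe, a lipid carrier of astrocytes, was at 2.90 ± 0.82 (SE), Itm2b at 2.31 and Apba2 at 2.59; 4 genes passed adjusted over the list alone and 0 over all genes tested. Autophagy and lysosome had 8 of 8 genes above 0 and a median of 1.87 (cameraPR adjusted p = 0.137). The median was 0.61 without centring and -0.31 relative to the abundant transcripts, again above that of all genes tested in each setting. Without the filter on missing values it had 18 genes and a median of 2.57, and was called (adjusted p = 1.2e-05). Its Atp6v1a, a subunit of the lysosomal proton pump, was at 3.20 and Lamp1 at 2.56. The gap between the medians of the abundant transcripts and the never-expressed families was 2.69, 2.62 and 2.62 at 12 months, 1.24, 1.89 and 1.19 at 3 months, and -0.61, -0.97 and -1.06 for WT ageing. The abundant transcripts are the 5 lists themselves, so this gap is not an observation separate from theirs.

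No single probe passed at 12 months. Enc1 was at 3.83 ± 0.77 (SE, n = 3 arrays, limma adjusted p = 0.258), Kcnab1, a potassium channel subunit, at 5.31, Tmem59 at 3.54, Clk1, a kinase of splicing factors, at 3.75, Sdcbp at 3.40, Tmem106b, a lysosomal membrane protein, at 3.31, Acyp1 at 3.32, G3bp2, a stress granule protein, at 4.19, Rgs7bp at 3.55 and Kif21a at 3.79. Below 0 were Ttr, the thyroid hormone carrier made by choroid plexus, at -3.50 ± 0.91 (SE), Rpgrip1 at -5.58, Sbf1 at -4.76, Cd3g at -3.83, Trak2 at -3.25, Olfr51, of the olfactory receptors taken above as never expressed, at -3.57, Tlr6 at -3.19, Dnase1l3 at -2.51, Cd6 at -2.83 and Clock at -2.52. All kept their sign without centring and with centring on the abundant transcripts, but not their size. The 10 above 0 ran from 3.31 to 5.31, from 2.14 to 4.04 without centring and from 1.12 to 3.05 relative to the abundant transcripts, where 2 of them kept an unadjusted limma p under 0.05. The 10 below 0 ran from -5.58 to -2.51, from -6.80 to -3.70 without centring and from -7.71 to -4.75 relative to the abundant transcripts. Sbf1 and Rpgrip1 were also named above 0 for WT ageing, at 6.16 and 3.79. The WT mice of 12 months are the test there and the reference here, so for these probes the results are not separate. limma called 0 of 3644 probes, with 607 at an unadjusted p under 0.05, 531 above and 76 below 0. Without centring it called 0, and of 392 at an unadjusted p under 0.05, 97 were above and 295 below 0. Centred on the abundant transcripts it called 0, and 24 were above and 945 below 0, so the overall direction turned with the centring.

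**Figure D2:**
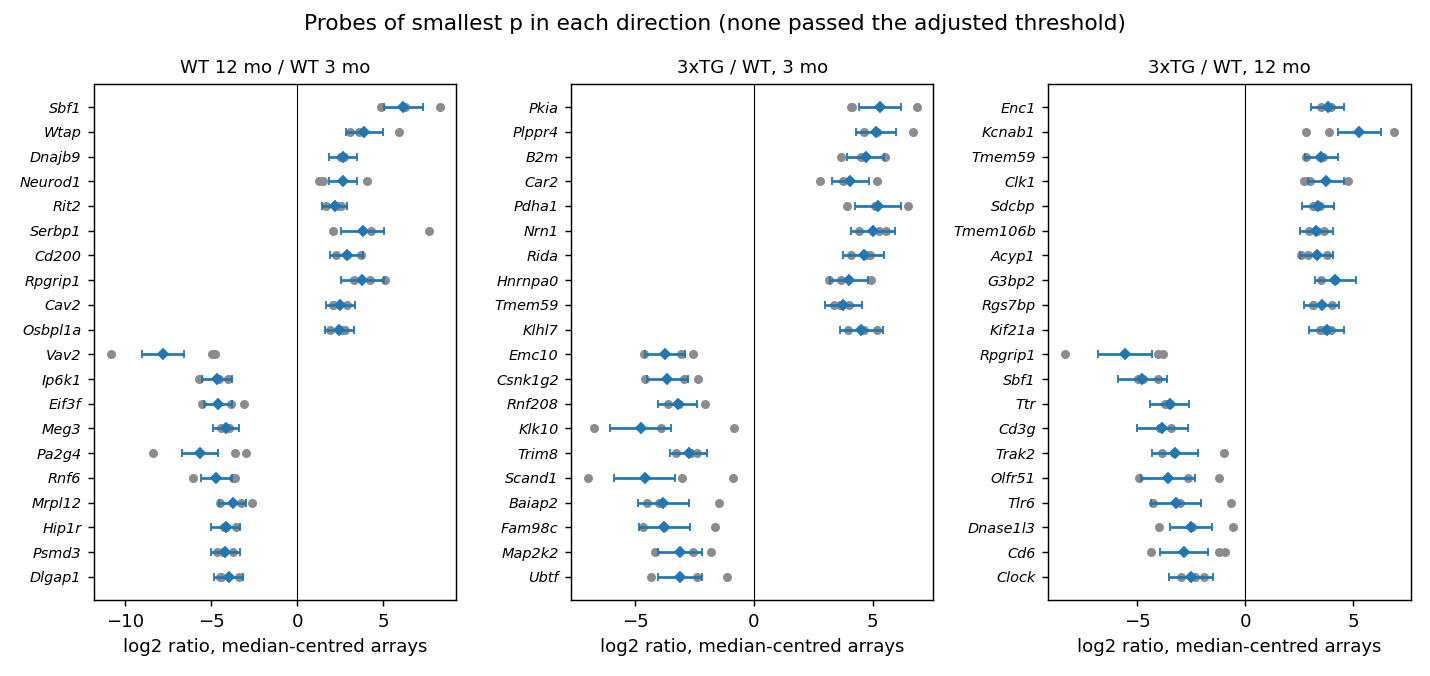
Log2 ratios relative to the array median (horizontal axis) of 20 probes per comparison. They are those of smallest p in each direction among probes with a gene symbol and one sign on all 3 arrays. Circles are the 3 arrays and diamonds the fitted value ± SE. No probe passed the adjusted threshold; in the third comparison Enc1 is at 3.83 and Ttr at -3.50.

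The genotype effect at 12 months minus that at 3 months had its smallest p at Csnk1g2, a casein kinase, with 6.81 ± 1.21 (SE, limma adjusted p = 0.712). Chrnb1 was at 4.87, Gpc1 at 5.10, Ccpg1 at 4.44 and Rgs7bp at 4.37; Wtap was at -4.53, Washc4 at -3.38, Dnajb9 at -2.64, Golm2 at -2.62 and Klhl7 at -2.81. These are the probes of smallest p among those with one sign on all 3 arrays at each age, and unadjusted limma p-values reached 0.0596. Without centring the 5 above 0 ran from 2.61 to 5.05 and the 5 below 0 from -6.26 to -4.36, and relative to the abundant transcripts from 2.85 to 5.32 and from -5.90 to -4.05. limma called 0 probes, with 253 at an unadjusted p under 0.05, and cameraPR called no list. Without centring limma called 0, with 280. Leaving out replicate 2 of WT at 12 over 3 months took the 253 to 137, where the nominal rate gives 180. It took the 607 for genotype at 12 months to 390. In that fit the ratio of between-mouse to between-array variance reached 10, the highest value allowed, against 1.02 with all arrays. The fall therefore cannot be laid to the values of that array alone. Complex I had a median difference of 1.37 (adjusted p = 0.523), or -0.13 without centring (adjusted p = 0.672), so its effect was not shown to differ between ages. For 3xTG at 12 over 3 months through WT, limma called 0 probes, with 205 at an unadjusted p under 0.05, and 216 without centring. The probes of smallest p among those with one sign within each of the 3 comparisons, with unadjusted limma p-values from 0.128 to 0.255, are not among the 205. Tmem106b was at 1.55, Clk1 at 1.63, Camta1 at 2.27, Gpc1 at 1.64 and Pkd2 at 1.52, and Atp2b1 was at -1.97, Tbcel at -1.50, Dnajc27 at -1.79, Laptm4a at -1.28 and Mrpl12 at -1.20. Relative to the abundant transcripts those above 0 ran from 0.57 to 1.10 and those below 0 from -2.98 to -2.16.

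Across the 3644 probes, which are not independent replicates, the genotype effects at 3 and 12 months, which share no mouse, correlated at 0.338 (simulated without effects, 0.0371). Their covariance was 1.27 against a simulated 0.10. WT ageing and genotype at 3 months share WT mice and correlated at 0.272 (simulated 0.29). WT ageing and genotype at 12 months correlated at -0.129 (simulated -0.196).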

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

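For 8 probes named above, all 3 arrays of the genotype comparison lay on one side of the array median at 3 months and all 3 on the other at 12 months. The rule that named them required one sign at each age and favoured a large difference between ages, so it favours such probes. The difference between ages was above 0 for Csnk1g2 (6.81), Chrnb1 (4.87), Gpc1 (5.10), Ccpg1 (4.44) and Rgs7bp (4.37) and below 0 for Wtap (-4.53), Washc4 (-3.38) and Dnajb9 (-2.64). The test of the difference itself passed for none of them (limma adjusted p = 0.712). The sides depend on the centring: 7 of the 8 lay on opposite sides of 0 without it and 5 with centring on the abundant transcripts, where the mean of Ccpg1 at 12 months was -0.07. Dnajb9 lay near the array median at 12 months, with a mean of -0.19. In WT ageing, Csnk1g2 was at -5.08, Gpc1 -3.46, Ccpg1 -3.62, Rgs7bp -3.70, Wtap 3.91, Washc4 2.12 and Dnajb9 2.68. These values are opposite in sign to the difference between ages, while that of Chrnb1, 2.00, is not. The WT mice compared there are the references here, so the difference cannot be placed in the 3xTG mice alone. Of 637 probes listed on all 6 genotype arrays, 42 (6.59%) had opposite signs at 3 and 12 months, and 301 had one sign on all 6. Independent signs on all arrays would give 3.13% opposite, but arrays of a comparison share mice and agreed more often. At 3 months 51.8% of probes, and at 12 months 50%, had one sign on all 3 arrays, where independence gives 25%. Among the probes with one sign at each age, 42 had opposite signs and 301 equal ones, so no excess of opposite signs was seen. Of the 10 splits of these 6 arrays, 3, the real one included, gave at least the real count of 253 probes at an unadjusted p under 0.05, and the highest other gave 340; 10 splits are too few for a share under 0.05.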

How the results depend on the processing

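Every setting left the 5 probe counts at 0 except those given next. Treating arrays as independent called 66 probes for WT ageing and 56 for genotype at 3 months. Testing the 142 probes listed on all 9 arrays called 21, 60 and 74 in the 3 hybridised comparisons; fewer probes were tested, and they are those whose ratio was large on every array. On gene means the reported setting called 0 genes, but scaling arrays to the same spread called 155 for WT ageing, and dropping the dye term called 47 for WT ageing and 11 for genotype at 3 months. Independent arrays called 35 and 23 genes, and the 516 complete genes gave 17, 27 and 20 calls in the 3 hybridised comparisons. Leaving out any 1 array gave 0 probes in each comparison, and lists from 0 to 1 for genotype at 12 months.

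The 1 list called for genotype at 12 months became 0 without centring, the setting fixed before the data were examined. It also became 0 with centring on the tested probes or the abundant transcripts, and with the 2 arrays that share no mouse. The same held with separate dye terms for the 2 slide runs and with turned signs. Complete genes alone also gave 0, but there only 1 list had 5 genes and complex I could not be tested. Without the filter on missing values 6 lists were called: complex I, complexes II to V, proteasome, autophagy and lysosome, GABA receptors, and calcium-binding and calcium-dependent signalling. Centrings other than the median and both list filters were chosen after seeing the data. The experiment number as a replicate block gave 0 lists and 0 probes; these numbers did not pair the arrays (correlation of same-numbered deviations -0.064 to 0.168). The cause of these changes was not tested.

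Reading ratios as Cy5 over Cy3, which the correlations between arrays contradict, reversed the complex I median to -0.30 and these probes. For WT ageing, Sbf1 was at -0.014, Wtap -0.22, Serbp1 -1.51, Cd200 -0.00375, Ip6k1 0.75, Meg3 0.34, Psmd3 0.33 and Dlgap1 0.45. At 3 months Plppr4 was at -0.47, Trim8 0.55 and Fam98c 0.40. At 12 months Tmem106b was at -0.38, G3bp2 -0.24, Rpgrip1 2.13, Sbf1 1.25, Ttr 0.030, Cd3g 0.69, Trak2 0.20 and Tlr6 0.32. For the difference between ages, Csnk1g2 was at -0.15, Chrnb1 -1.28, Rgs7bp -0.46 and Washc4 0.19. Through WT, Tmem106b was at -1.39, Camta1 -1.55, Pkd2 -0.69, Atp2b1 0.84 and Dnajc27 0.71. Signal over background, which limits these ratios, is unknown.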

Other observations

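The tests of the complex I call and of the never-expressed families were chosen after those results had been seen. The 12 complex I genes had a mean log2 ratio of 1.98 at 12 months, and the 32 tested genes of the other 4 lists of abundant transcripts 1.47. The difference of 0.52 did not pass (two-sided permutation test over genes, p = 0.222), so an offset common to abundant transcripts may account for the call, and it cannot be told apart from a change in complex I with these genes. Dye bias alone is argued against: 0 of the 3 comparisons had both signs of the gap between abundant and never-expressed probes among its arrays, although each holds both dye orientations. A difference in RNA quality or labelling between the mice, and the genotype itself, stay open and were not tested.

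Probes of the never-expressed families spread as widely as all probes, with SDs of 2.00 to 2.55 against 2.14 to 2.42. Their median correlation between arrays of one comparison was 0.0114, against 0.276 for all probes, consistent with ratios formed near background. No biological explanation was tested.

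The correlation of the genotype effects at 3 and 12 months was 0.336 without the genes of the 5 lists of abundant transcripts. The highest simulated value was 0.0899. Complex I has 12 tested genes and the other lists 32, too few to move a correlation across 3644 probes by much. Their removal therefore cannot decide whether an offset common to abundant transcripts accounts for the correlation. Such an offset, and an effect of genotype at both ages, stay open.

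Of the 4 sign patterns of the 3 arrays, 1, the real one, gave as many probes at an unadjusted p under 0.05 in each hybridised comparison. The real counts and the highest others were 431 and 298 for WT ageing, 492 and 262 at 3 months, and 607 and 279 at 12 months. With 4 patterns no share under 0.05 can be reached.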
